A study of Oryza sativa with 4 samples.

How the data were processed

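RNA from rice suspension cells was hybridised to 4 two-colour oligonucleotide arrays, 2 for wild-type cells and 2 for cells carrying an RNA interference construct against CEBiP. Per the labels, each array held chitin-treated RNA in one dye and untreated RNA of the same genotype in the other, with the dyes exchanged between the 2 arrays of a genotype. The labels give no dose or duration of the treatment.

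The scanner output of each array gave the mean intensity of each spot and the median intensity of its local background in Cy3 and Cy5 on a linear scale, per the file headers. The deposited files also held processed intensity values, already background-subtracted and dye-normalised within the array by Agilent Feature Extraction, and a log10 ratio of Cy5 over Cy3 from the same software, per the file headers. The submitters' processing notes name version 6 of this software and the file headers name A.7.1.1. The submitters also deposited a table of log10 ratios. Set against the scanner output, each of its columns was the software's log10 ratio with the sign turned to treated over untreated, within 0.005 for 100% of the spots, with column medians of 0, -0.02, 0 and -0.0118. This match settles the table's scale, centring and direction up to rounding.

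Mean and background intensities were corrected with normexp at an offset of 50 and normalised within each array by loess, with limma 3.58.1 in R 4.3.3. Control spots and spots marked as outliers by the software had weight 0 in the loess. Each ratio was turned to treated over untreated, converted to log2 and averaged over the 2 dye orientations of a genotype. Levels in single channels were taken after loess and Aquantile, and untreated RNA of the genotypes was compared Cy5 with Cy5 and Cy3 with Cy3. Features were kept if no spot was marked as an outlier on any array and if at least 1 channel was well above background on both arrays of at least 1 genotype. This left 13602 of 21495 features, with 7881 left out for an outlier mark and 12 for signal. Each accession had 1 probe. The share of features marked was 10.8% and 0.7% on the wild-type arrays and 24.7% and 6.1% on the knock-down arrays.

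The number of arrays limits the precision. The dye swaps were counted as 1 replicate per genotype because nothing in the labels says that they came from separate cultures, so no test across conditions was possible. A feature was called when it was at least 2-fold higher, or 2-fold lower, on each of the 2 arrays, or for a difference between genotypes in both dye orientations. The technical standard deviation of a log2 ratio on 1 array was estimated from the difference between genotypes of the dye-orientation contrasts. It was 0.312 in the dimmest eighth of features and 0.077 in the brightest. No feature named in the text was saturated, or not well above background, on every array of a genotype in the channel that held its RNA. Negative-control spots had median intensities of 201.3 to 254.7 in Cy3 and 93.2 to 278.7 in Cy5, above the local backgrounds of 52 to 68, so the software's mark for signal above background is a lenient one.

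The comparisons, size rule, gene lists, most alternatives and the rule for naming features were fixed before the data were examined. Named features are, per comparison, the 10 with the largest and the 10 with the lowest mean log2 value among those called and described as an identified gene or protein, and the 2 members of each list with the largest wild-type response of either sign. Members of a list beyond these that are named as examples, and the features named for the retained response, were chosen after their values were seen. The 30 lists were searches of the feature descriptions. They covered chitin receptors and LysM proteins, phenylpropanoid, shikimate, diterpenoid and other metabolic enzymes, pathogenesis-related proteins, transcription factors, signalling proteins, transporters, growth functions, housekeeping genes and proteins of other rice tissues. The list of chitin receptors and LysM proteins matched 0 features. Such searches miss a feature whose description uses other words, so 0 matches do not show that no such protein was measured. A list's median was placed among 10000 random lists of the same size, matched on brightness in 20 bins, and called when it lay below percentile 2.5 or above 97.5. This describes these arrays and is no test across conditions. Of 116 list medians 38 were called, where 5.8 would be by chance for independent lists. A reference table of rice genes matched 0 of the accessions, so no gene positions are given. Several features can stem from the same gene.

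The calling rule was tested on simulated data, as was limma. In simulated wild-type data with 200 of 13602 features changed, limma with the arrays as samples recovered 83 with 0 false calls, and with a term for dye orientation 199 with 1 false call. The arrays simulated for limma held a repeating dye bias and technical noise, with no differences between cultures.

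Alternatives were no background subtraction, normexp with an offset of 10, the software's processed signals, median centring, other filters on dim features, no between-array step or quantile normalisation for single channels, a limit of 3-fold, a limit on the mean alone, each array left out, picking features on 1 wild-type array, unmatched random lists, the deposited ratio table, and limma with the arrays as samples. Added after the data were examined were outlier spots kept, a filter at percentile 95 of the negative-control spots, those spots as background, and picking features on 1 knock-down array. Counts and lists were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.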

Results

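The series measured messenger RNA levels in suspension-cultured rice cells with and without chitin oligomers, short chains of N-acetylglucosamine that plant cells perceive as a sign of fungal attack. The cells were either wild type (cultivar Nipponbare) or carried an RNA interference construct against CEBiP, a plasma membrane protein that binds chitin fragments. Per the labels the study asked what CEBiP contributes to chitin signalling. There were 4 two-colour arrays, 2 per genotype, and each array held treated RNA in one dye and untreated RNA of the same genotype in the other. The dyes were exchanged between the 2 arrays of a genotype. The labels call the second array of each genotype a colour swap and name no separate cultures, so the 2 arrays were counted as 1 replicate and no condition has a biological replicate. A feature was called higher or lower when it differed by at least 2-fold in the same direction on each of the 2 arrays, which is a rule of size and not a test. Values are log2 ratios, given as the mean of the 2 arrays or with the value of each array. Of 21495 cDNA features, 13602 were measured on all 4 arrays. Features carry a cDNA accession and the description of a similar sequence, often from another plant, and are named here by that description. No description named CEBiP, so the level of the targeted RNA was not analysed here and the knock-down label was not checked in these data.

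After chitin treatment the wild-type cells had higher mRNA levels for some of the enzymes that make phenylpropanoids, the phenolic compounds of lignin and plant defence. A feature described as inducible phenylalanine ammonia-lyase (AK068993), the entry enzyme of that pathway, had log2 ratios of 5.03 and 5.59 on the 2 arrays, a mean of 39.6-fold. Cinnamate 4-hydroxylase (AK072588), which acts on the product of that enzyme, had a mean of 3.81, and 4-coumarate-CoA ligase 4CL3 (AK070083) had 4.09 and 4.10. Cinnamoyl-CoA reductase (AK072872) at 3.65 and caffeoyl-CoA 3-O-methyltransferase (AK071482) at 3.54 belong to the lignin branch. In all, 12 of the 38 measured features of this list were higher, 0 were lower and 26 passed in neither direction. The list median was 0.46, at percentile 100 among 10000 random lists of the same size and brightness. The shikimate list, whose enzymes supply the aromatic amino acids, had 8 of 17 features higher and 0 lower, with a median of 1.10 at percentile 100. Its strongest members were a pair of features for 3-deoxy-D-arabino-heptulosonate 7-phosphate synthase, the entry enzyme of the shikimate pathway, at 3.85 (AK059247) and 3.70 (AK105687), followed by tryptophan synthase alpha (AK066734) at 3.33 and shikimate kinase (AK066687) at 3.14.

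Some features for defence proteins and signalling components were also higher in the treated wild type. Of 78 features for pathogenesis-related proteins, 13 were higher, 1 was lower, and the median was 0.22 at percentile 100. They included a thaumatin-like protein (AK099946) at 3.65 and chitinases (AK102505, AK106319), enzymes that cleave chitin, at 3.57 and 2.62. The lower feature was a glucanase-like protein (AK101322) at -1.24. Of 21 MAP kinase cascade features 8 were higher and 0 lower (median 0.61, percentile 100). MAP kinase 1 (AK067339) reached 3.95, and 1 of the 8, a MAP kinase phosphatase (AK071054, 1.41), belongs to a class that switches such kinases off. Among 47 calcium signalling features 9 were higher and 0 lower (median 0.29, percentile 100), with EF-hand protein CCD1 (AK111852) at 2.95 and a calcium-dependent protein kinase (AK072204) at 2.59. Of 193 receptor-like kinase features 21 were higher and 2 lower, with a median of only 0.09 (percentile 99.9). The search also caught a receptor for activated C-kinase (AK062179), by its description no receptor kinase, and it was 1 of the 2 lower features, at -1.16. A receptor protein kinase (AK100082) had 4.33 and the PR5K-like kinase (AK110482) had 3.34.

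Transcription factor groups and jasmonate enzymes had higher members in the wild type as well. Of 26 NAC features 8 were higher and 0 lower (median 0.35, percentile 100), with OsNAC4 (AK073848) at 3.52. Of 22 WRKY features 5 were higher and 0 lower (median 0.35, percentile 99.96), with a WRKY6-like factor (AK105509) at 3.37. Of 35 MYB features 5 were higher and 0 lower (median 0.16, percentile 98.4; 88.5 without the array with treated RNA in Cy3), and a MYB factor (AK112056) had 4.62 and 4.83 on the 2 arrays. Of 23 jasmonate and oxylipin features 5 were higher and 0 lower (median 0.31, percentile 99.95; -0.001 and 57.0 without the array with treated RNA in Cy5, and percentile 96.9 with outlier spots kept), among them allene oxide synthase (AK068620), which commits a fatty acid hydroperoxide to jasmonate synthesis, at 2.66.

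Among all features with a named description, the largest mean wild-type ratio belonged to HIN1 (AK068115), a tobacco gene known from the hypersensitive response, at 5.30 and 5.48. A nodulin-like protein (AK070844) had 5.25, a blue copper protein (AK063639) 4.69, serine palmitoyltransferase (AK069007), the entry enzyme of sphingolipid synthesis, 4.64, a PDR5-like ABC transporter (AK073104) 4.43 and pirin (AK105971) 4.39. The strongest lower features were an alanine:glyoxylate aminotransferase (AK060423) at -3.65 and -2.74 and a lipid transfer protein (AK071598) at -3.63 and -2.58. Beta-expansin EXPB3 (AK100959), which loosens cell walls, had -2.26. Also lower were dUTPase (AK063633) at -2.22, replication protein A1 (AK060582) at -2.06 and ribonucleotide reductase R2 (AK073063) at -1.42.

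Among the lists for growth, those of ribosomal proteins, histones and cyclins had medians below 0 in the wild type. Cell wall growth enzymes did not (median 0.12, percentile 99.3; 45.8 without the array with treated RNA in Cy3). Of 114 cytosolic ribosomal protein features 8 were lower and 0 higher, and the median was -0.67, at percentile 0.0. A ribosomal protein L24 (AK101927) had -1.49 and 60S ribosomal protein L1 (AK060711) had -1.48. Of 22 histone and DNA replication features 4 were lower and 0 higher (median -0.24, percentile 0.33; 3.41 with outlier spots kept), including histone H4 (AK059019) at -1.54. Of 48 cyclin and cell division features 1, a D-type cyclin (AK103499) at -1.48, was lower (median -0.27, percentile 0.0). The housekeeping list, of actins, tubulins, ubiquitins and the like, had a median of -0.20 (percentile 0.38; 3.55 without the array with treated RNA in Cy5), with 2 features higher and 2 lower. An actin feature (AK068991) stood at 2.49.

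Across the array 611 features were higher and 135 lower in the wild type after chitin. With outlier spots kept the counts were 951 and 168, and with a 2-fold limit on the mean alone 791 and 234. The rule was tested on simulated wild-type data with 13602 features. It recovered 39 of 50 features set at a log2 change of 1.5, all 50 set at 2 and 49 of 50 set at -2. It called 0 of 13402 unchanged features. Without replicate cultures there was no measure of differences between cultures to simulate, so these numbers give no false-call rate for the 611 and 135 features. With limma and the arrays taken as samples, 587 features were higher and 159 lower at a Benjamini-Hochberg adjusted p of 0.05, and with dye orientation as a block 1625 and 1388. These counts measure labelling and hybridisation spread only. On the array with treated RNA in Cy3 alone, 800 features were higher and 439 lower, and on the other array alone 1382 and 457.

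In the knock-down cells 406 features were higher and 151 lower after chitin treatment. The blue copper protein (AK063639) had 3.64 and 4.13 on the 2 arrays, and a putative protein kinase (AK108910, described by Arabidopsis At2g33580) had 3.70. A DNA-binding protein described by Avena fatua clone ABF2 (AK106282) had 3.67, the receptor protein kinase (AK100082) 3.40, HIN1 (AK068115) 3.28 and a beta-1,3-glucanase (AK058891) 3.23. Calreticulin (AK060834), a calcium-binding chaperone of the endoplasmic reticulum, had 3.45 and 4.01 here against 1.27 and 2.07 in the wild type. Of the 26 NAC features 9 were higher and 1 lower (median 0.23, percentile 99.9), with OsNAC4 (AK073848) at 3.22 and OsNAC7 (AK102224) as the lower feature at -2.12. Of the 47 calcium signalling features 9 were higher and 0 lower (median 0.31, percentile 100). Of the 193 receptor-like kinases 15 were higher and 1 lower (median 0.02, percentile 77.0), of the 22 WRKY features 4 were higher and 0 lower (median 0.11, percentile 94.8), and of the 78 pathogenesis-related features 10 were higher and 2 lower (median 0.02, percentile 71.7). The MYB list had 3 higher and 0 lower (median 0.10, percentile 97.1), 1 of them a TOM-like protein (AK067871) that is no MYB factor itself. The jasmonate list had 4 higher and 0 lower (median 0.07, percentile 86.9).

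In the knock-down, of the 38 phenylpropanoid features 6 were higher and 0 lower (median 0.20, percentile 99.96), including a hydroxycinnamoyl transferase (AK060705) at 2.99 and a cinnamoyl-CoA reductase (AK064401) at 2.17. Of the 17 shikimate features 4 were higher and 0 lower (median 0.68, percentile 100), and of the 21 MAP kinase cascade features 2 were higher and 0 lower (median 0.26, percentile 99.95). The ribosomal protein list had 0 features past the limit and a median of -0.18 (percentile 0.0), the histone list 0 and -0.12 (percentile 4.2), the housekeeping list 1 higher and -0.07 (percentile 7.7), and the cyclin list 1 lower and -0.21 (percentile 0.0).

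The features named next were picked for low values on the knock-down arrays, which by itself favours values nearer 0 in the wild type. A farnesylated protein (AK064565) and a cystatin (AK102139), a protease inhibitor, both had -3.08 against -1.05 and -0.86 in the wild type. A preproMP73-like protein (AK102651) had -2.85 against -0.26, and a cationic peroxidase (AK101508) -2.78 against -1.44. A nonspecific lipid transfer protein (AK063729) had -2.58 against 0.43. In untreated cells AK063729, AK102139 and AK064565 were already higher in the knock-down, by 3.20, 1.67 and 1.04. For AK102651 and AK101508 the untreated difference was 0.755 and 0.179. A lower ratio here therefore does not by itself show a lower treated level than in the wild type. EXPB3 (AK100959) had -2.26, nearly its wild-type value. With limma and arrays as samples, 261 features were higher and 94 lower in the knock-down at an adjusted p of 0.05, and with dye orientation as a block 1018 and 661. On 1 array alone the numbers were 642 to 753 higher and 368 to 373 lower.

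Of the features higher in the wild type, 298 were also higher in the knock-down, where independent sets of these sizes would share 18.2. For lower features the shared number was 40, against 1.5. The mean responses of the genotypes correlated at r = 0.673 across the 13602 features, which are not independent replicates.

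**Figure D1:**
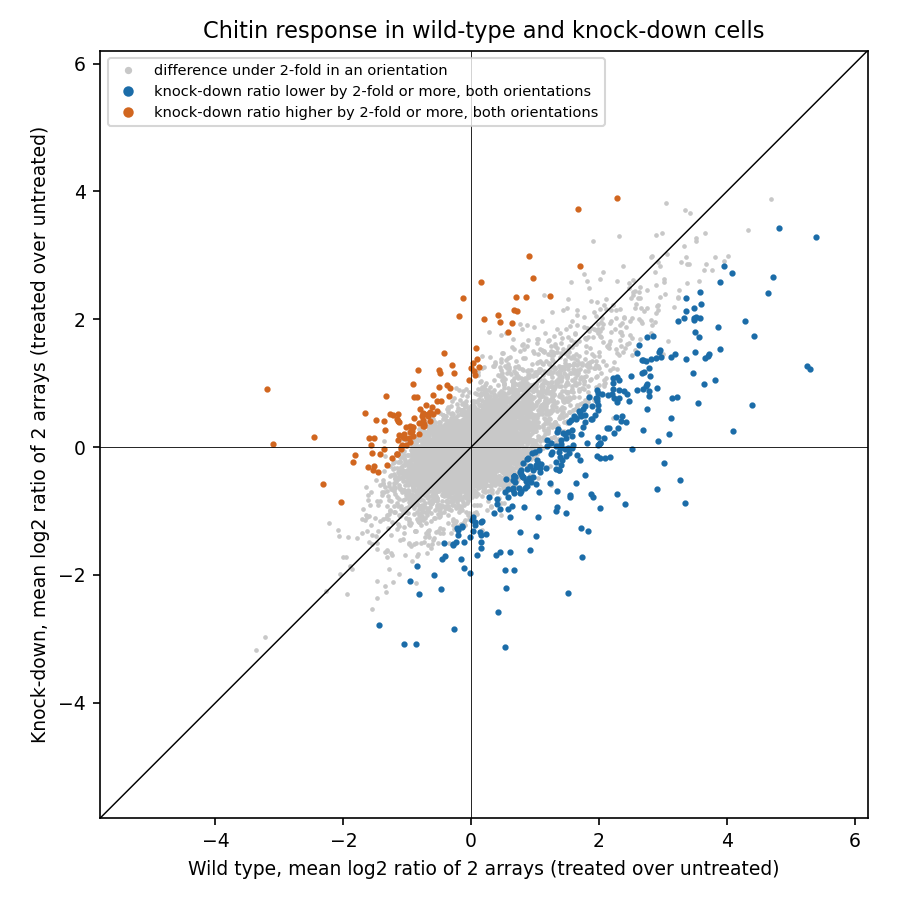
Mean log2 ratio of chitin-treated over untreated RNA in the wild type (horizontal axis) and the knock-down (vertical axis), 1 point per feature, with the line of equal response. The 294 features whose ratio was at least 2-fold lower in the knock-down in both dye orientations lie below the line, and the 114 features with a higher ratio lie above it.

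The response itself was then compared between genotypes, array against array of the same dye orientation. A smaller or larger ratio is a lower or higher signed log2 ratio in the knock-down, whichever way the feature responded. A deeper fall in the knock-down thus counts as a smaller ratio. Several enzymes of aromatic metabolism were among the features with a much smaller ratio in the knock-down. Phenylalanine ammonia-lyase (AK068993) had 5.31 in the wild type and 1.23 in the knock-down, a difference of -4.08, and another phenylalanine ammonia-lyase feature (AK102817) had 2.90 and -0.65. The 4CL3 feature (AK070083) had 4.09 and 0.26, cinnamate 4-hydroxylase (AK072588) 3.81 and 1.05, and an isoflavone reductase-like protein (AK109339) 2.41 and -0.89. Large negative differences were also seen outside this pathway. They were -3.98 for the nodulin-like protein (AK070844), -3.79 for pyruvate orthophosphate dikinase (AK065739), -3.78 for the glycine-rich protein CAI1 (AK063328) and -3.74 for pirin (AK105971). The dikinase had 1.51 in the wild type and -2.28 in the knock-down. Of the 38 phenylpropanoid features 12 had a smaller ratio and 1 a larger ratio in the knock-down, and the median difference of -0.37 lay at percentile 0.0. The feature with the larger ratio was a hydroxycinnamoyl transferase (AK101900), at -0.48 in the wild type and 0.71 in the knock-down. Of the 17 shikimate features 5 were smaller and 0 larger (median difference -0.35, percentile 0.07), with shikimate kinase (AK066687) at 3.14 and 0.76.

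Other defence groups had smaller median differences. For pathogenesis-related proteins 5 of 78 features were smaller and 0 larger (median difference -0.17, percentile 0.02). The chitinase AK102505, at 3.57 and 2.60, was not among the 5. For peroxidases and NADPH oxidases 5 of 55 had a smaller ratio and 0 a larger one (median difference -0.20, percentile 0.01, and 3.60 with outlier spots kept). Among the 5, the cationic peroxidase AK101508 (-1.44 and -2.78) and a peroxidase (AK073978, -0.41 and -1.70) fell further in the knock-down. In that list 5 features were higher and 1 lower in the wild type (median 0.08, percentile 88.7), while 0 were higher and 4 lower in the knock-down (median -0.01, percentile 37.5). A peroxidase (AK069456) had 3.47 and 1.16, and the cationic peroxidase OsCPX1 (AK102307) had 2.23 and 0.22. WRKY features had a median difference of -0.23 (percentile 0.62) with 0 past the limit either way, a list result that ended with median centring (percentile 2.93). Receptor-like kinases had a median difference of -0.06 (percentile 1.49; 5.26 and 12.8 with only the orientation with treated RNA in Cy5 or in Cy3), with 5 smaller and 2 larger, AK062179 again being 1 of the latter. NAC features had 0 smaller and 0 larger (median difference -0.02, percentile 35.7), and calcium signalling features 1 smaller and 0 larger (median difference -0.08, percentile 8.5). The MYB list had 3 smaller and 0 larger (percentile 11.9) and the MAP kinase list 2 and 0 (percentile 16.3).

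Some features responded more, or were less lowered, in the knock-down. The aminotransferase AK060423 had -3.20 in the wild type and 0.91 in the knock-down, and the lipid transfer protein AK071598 had -3.10 and 0.05. The lipid transfer protein precursor LTP2 (AK058896) had 0.15 and 2.58, and calreticulin (AK060834) 1.67 and 3.73. The ratio of the chaperone HSP90 (AK102478) was 0.20 in the wild type and 1.79 higher in the knock-down. The ribosomal protein list had 5 features larger and 0 smaller, with a median difference of 0.40 at percentile 100. Other lists shifted the same way, namely housekeeping (median difference 0.13, percentile 98.4; 97.2 and 95.8 with only the orientation with treated RNA in Cy5 or in Cy3) and cyclins (0.11, percentile 99.1; 93.9 with only Cy5 and 77.0 with outlier spots kept). Each had 1 feature larger and 0 smaller.

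In all, 294 features had a smaller and 114 a larger ratio in the knock-down. With median centring in place of loess the split was 235 and 198, and on single orientations 423 and 211 (treated RNA in Cy3) or 760 and 206 (Cy5). Of the 294, 181 were higher in the wild type, 44 were lower in the knock-down, and 72 passed the limit in neither genotype. No single feature's difference passed a test across arrays. Here limma with the arrays as samples called 0 features at an adjusted p of 0.05 and, at an unadjusted p of 0.05, 597 smaller and 399 larger. With dye orientation in the model the adjusted count was also 0, and the unadjusted counts were 1539 and 1359. Genotype, cell line and array could not be separated, as each array held 1 genotype.

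**Figure D2:**
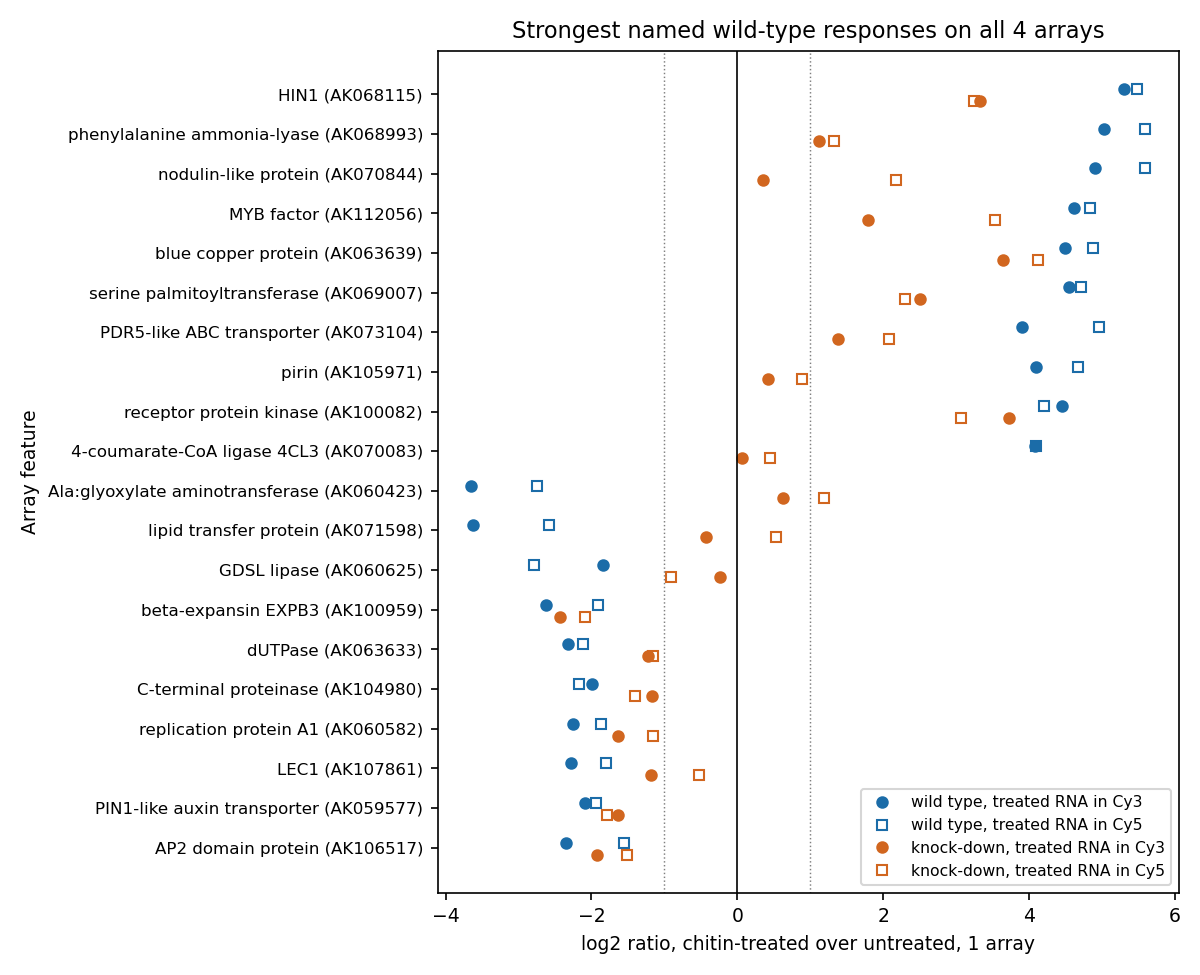
Log2 ratio of treated over untreated RNA on each of the 4 arrays for the 10 named features with the largest and the 10 with the lowest mean wild-type ratio. Dotted lines mark 2-fold; phenylalanine ammonia-lyase (AK068993) lies at 5.03 and 5.59 in the wild type and at 1.12 and 1.33 in the knock-down, while EXPB3 (AK100959) has means of -2.26 in both.

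How much of the wild-type response was present in the knock-down was measured over the features picked in the wild type. The 611 higher features had a median of 1.82 in the wild type (1.80 and 1.86 on the 2 arrays) and 1.16 in the knock-down (1.16 on each), a ratio of medians of 0.638. For 227 of them, 37.2% (95% Wilson interval 33.4 to 41.1, counting error only), the knock-down ratio was under 0.5 times the wild-type ratio. These included phenylalanine ammonia-lyase, 4CL3, pirin and the nodulin-like protein. The knock-down ratio was at or above the wild-type ratio for 73, including OsNAC3 (AK073667) at 2.16 against 2.11 and a receptor-like kinase (AK063805) at 2.99 against 2.83. The 135 lower features had a median of -1.35 in the wild type and -0.70 in the knock-down, and 63 of them (46.7%, interval 38.5 to 55.1) were under 0.5 times the wild-type ratio. Features picked for a large value fall back when measured again. Picked on the wild-type array with treated RNA in Cy3 alone, 800 features had a median of 1.63 on the other wild-type array and 0.91 on the knock-down array of that orientation. Picked on the other wild-type array, 1382 features had 0.80 and 0.30. The loss depended on which genotype picked the features. Picked on 1 knock-down array, a choice made after seeing the data, 642 and 753 higher features had 1.38 and 0.98 on the wild-type array of the other dye orientation and 1.27 and 1.10 on the knock-down array. The 406 picked on both knock-down arrays had 1.80 in the wild type and 1.67 in the knock-down, so for these the wild type was higher although the knock-down had picked them. Lower features were nearer 0 in the genotype that did not pick them. The 151 picked on both knock-down arrays had -1.48 there and -0.70 in the wild type, so no smaller response of lower features can be read from the medians of the 135. The share under 0.5 times was 45.1% and 61.4% for the 800 and 1382 features, measured on the array that picked them.

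**Figure D3:**
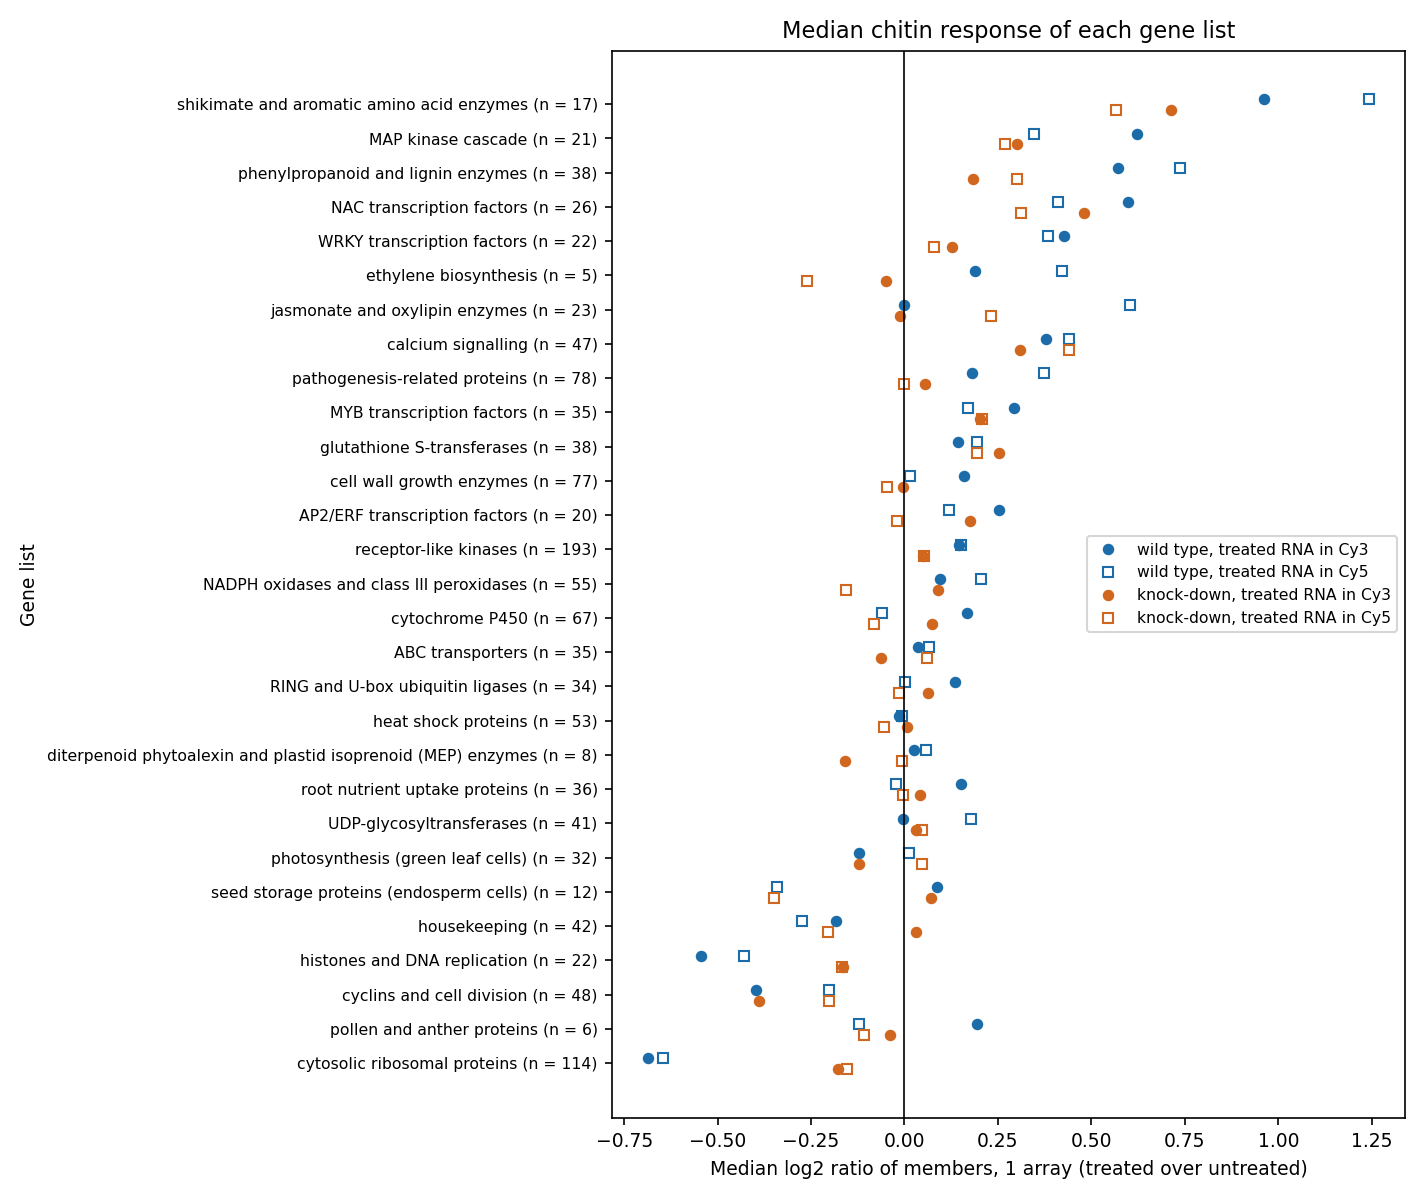
Median log2 ratio of the measured members of each gene list on each of the 4 arrays, with the number of members. Shikimate enzymes lie highest and cytosolic ribosomal proteins lowest in the wild type, where their medians over array means were 1.10 and -0.67, and the knock-down medians were 0.68 and -0.18.

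Untreated RNA was compared between genotypes in the same dye, to see where the cells differed before chitin. A 12-oxophytodienoic acid reductase feature (AK105590), of the family that includes a jasmonate synthesis enzyme, was 3.66 and 4.23 higher (log2) in the knock-down in the 2 dyes. Another feature with the same description (AK061212) was higher by only 0.08 in the mean. The nonspecific lipid transfer protein AK063729 was higher by 3.20, cytosolic pyruvate orthophosphate dikinase (AK065739) by 1.85, phosphoenolpyruvate carboxykinase (AK103839), an enzyme of gluconeogenesis, by 1.83, and the cystatin AK102139 by 1.67. Features lower in the knock-down were a tyrosyl-tRNA synthetase (AK101379) at -2.96, the rubisco large subunit (AK058623), a plastid gene, at -2.60, a receptor-like kinase (AK105581) at -1.85 and OsCPX1 (AK102307) at -1.40. Glutathione S-transferases had 4 of 38 features higher and 0 lower (median 0.18, percentile 99.2; 96.5 with median centring, 75.2 with outlier spots kept and 94.8 in Cy5 alone). Pathogenesis-related proteins had 4 of 78 higher and 0 lower (median 0.04, percentile 62.7), among them the probenazole-inducible protein PBZ1 (AK071613) at 1.30 and the chitinase AK102505 at 1.11. Ribosomal proteins had a median of -0.19 (percentile 0.0). Phenylpropanoid enzymes had 1 feature higher and 1 lower (median 0.08, percentile 81.0) and shikimate enzymes 0 and 0 (median 0.08, percentile 72.8).

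Over the array 92 features were higher and 35 lower in untreated knock-down cells. These values compare different arrays, so any difference between hybridisations enters them, and they share the untreated knock-down RNA with the knock-down response. With the software's processed signals the counts were 196 and 108, without background subtraction 47 and 17, and in a single dye 312 and 237 or 347 and 356, so that in Cy5 alone the lower ones were more numerous.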

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

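The tests of explanations for the smaller knock-down response were written before their results were seen, apart from picking on the knock-down arrays. Opposite responses were sought on all 4 arrays. A feature described as a thaumatin-like pathogenesis-related protein (AK102970) had ratios of 1.79 and 1.64 on the wild-type arrays and -1.32 and -1.21 on the knock-down arrays, with a knock-down mean of -1.26. Cytosolic pyruvate orthophosphate dikinase (AK065739), which interconverts pyruvate and phosphoenolpyruvate, had a mean of 1.51 in the wild type and -2.28 in the knock-down. A feature described as an unknown protein (AK063917) had 1.73 and -1.72. All 3 were at least 2-fold higher in the wild type and at least 2-fold lower in the knock-down on each array, and their untreated levels were higher in the knock-down by 1.06, 1.85 and 1.05. The difference in response was not tested across cultures. With limma and the arrays as samples the adjusted p of the difference was 0.173, 0.145 and 0.183, and with dye orientation in the model 0.0506, 0.0505 and 0.0505.

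The response in the knock-down was smaller for many features that were higher in the wild type. Selection of chance-high values of single wild-type arrays is argued against as the whole account, because on arrays not used for picking the wild-type median still exceeded the knock-down median by 0.724 and 0.497. The size of the loss is less certain, as features picked on 1 knock-down array gave gaps of 0.115 and -0.122, and those picked on both 0.133. Selection of differences between single cultures therefore stays open as part of it. A higher starting level in untreated knock-down cells is also argued against as the account of the typical loss. The median untreated difference was 13.5% of the median loss among the 181 wild-type-higher features with a smaller ratio. A median does not exclude a higher starting level for single members. The dikinase AK065739 had an untreated difference of 1.85 and a response difference of -3.79, while AK068993 and AK070083 were lower in untreated knock-down cells. Features with a smaller ratio that were not higher in the wild type were outside this test. A uniform compression of the knock-down ratios with technical error alone is argued against. With a best single factor of 0.592, 75.5% of the 611 features lay over 2 technical standard errors from it. This passed the limit set beforehand against a single factor. With 1 culture per genotype, however, that spread also holds differences between cultures, which the technical error does not measure. A uniform compression together with such differences cannot be told apart from a response that fell short for some genes only. It also stays open that the cell lines may differ for reasons other than CEBiP, such as transformation or culture state, because the labels name no separate lines or cultures within a genotype. A reduced CEBiP level is the explanation the design names, and it remains untested in these data.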

How the results depend on the processing

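The 12 summary counts, medians and shares were labelled as moved in 79 of their values under alternatives and as near in 119. Counts and medians had no common limit for a move, so these totals do not compare sizes of change. The knock-down median of wild-type-higher features, 1.166 with outlier spots kept against 1.163, was labelled as moved. The number of features higher in the knock-down, 319 without background subtraction against 406, was labelled as near. With only 1 wild-type array kept, list medians ran from -0.001 to 0.60 for jasmonate enzymes and from -0.12 to 0.19 for pollen proteins, so both changed sign without the array with treated RNA in Cy5. Leaving out 1 array moved 6 to 10 of 10 summary values, and a limit of 3-fold moved 11 of 12. With 1 array left out, higher features numbered 800 to 1382 and lower ones 439 to 457 in the wild type, and 642 to 753 and 368 to 373 in the knock-down. Smaller knock-down ratios numbered 423 to 760 and larger ones 206 to 211. Untreated differences numbered 312 to 347 higher and 237 to 356 lower, with more lower than higher in Cy5 alone. The knock-down median of wild-type-higher features ranged from 0.50 to 1.16 and of lower ones from -0.75 to -0.32, and the shares under 0.5 times the wild type from 36.5% to 61.4% and from 46.7% to 70.7%. Without the wild-type array that had treated RNA in Cy3, 1382 features were higher and 61.4% were under 0.5 times. Each of these rests on a single dye orientation, where probe dye bias does not cancel. Picking on 1 wild-type array gave knock-down medians of 0.91 and -0.18, or 0.30 and -0.13. Picking on 1 knock-down array, chosen after seeing the data, left gaps between the genotypes of 0.115 and -0.122 for higher features, against 0.724 and 0.497. A limit of 3-fold gave 314 and 20 features in the wild type and 178 and 38 in the knock-down. It also gave 102 smaller and 19 larger ratios and 13 and 5 untreated differences. Its medians were 1.57 and -1.40, and these and its counts follow from its own construction. Its share for lower features, over only 20 features, was 35.0%, and the cause of that change was not tested. A 2-fold limit on the mean alone gave 234 lower wild-type features, 163 and 77 untreated differences and medians of 1.05 and -0.62. For the other changes the cause was not tested. Processed signals gave 196 and 108 untreated differences and a median of 1.21, no background subtraction 47 and 17 and 1.07, and an offset of 10 gave 168 and 68, with medians of 1.23 and -0.74. Median centring gave 198 larger ratios and a median of 1.29. Outlier spots kept, an alternative chosen after seeing the data, tested more features and gave 951 higher features in the wild type and 612 in the knock-down. This alternative also gave 450 smaller ratios, 149 higher untreated levels and medians of 1.17 and -0.75. Those on negative-control spots, also chosen then, moved none of the 12. With limma and arrays as samples 261 features were higher and 94 lower in the knock-down, and smaller and larger ratios were 0 and 0 (597 and 399 at an unadjusted p of 0.05). With dye orientation as a block these were 1625 and 1388 in the wild type, 1018 and 661 in the knock-down, and 0 and 0 (1539 and 1359 unadjusted). The replicate numbers follow accession order and match no cultures across genotypes, so this block is dye orientation alone. Of 38 list calls, 33 held under every scaling, and 37 held with random lists not matched on brightness. The glutathione S-transferase lists, the cell wall lists and the WRKY difference lost a call under some scaling, and 5 calls ended with outlier spots kept. Of the 29 calls that use the wild-type arrays, 7 ended without the array with treated RNA in Cy3 and 6 without the other, beside the 2 that changed sign. Of the 21 that use the knock-down arrays, 4 ended without the array with treated RNA in Cy3 and 5 without the other. Of 131 calls or values of named features, run under scalings only, 4 each weakened with median centring and without background subtraction, and with processed signals 1 weakened and 1 passed the limit anew. Each accession had 1 probe, so treating probes apart moved nothing, and the CEBiP level was not run. Signal over background limits dim features, where the technical standard deviation reached 0.312.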

Other observations

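The tests of dye orientation below were chosen after the result was seen, and those on ribosomal proteins before, apart from the use of an interval. Further gene lists showed mixed behaviour. Of 38 glutathione S-transferases, enzymes that conjugate foreign and reactive compounds, 5 were higher and 1 lower in the wild type (median 0.15, percentile 97.8) and 3 higher and 1 lower in the knock-down (median 0.19, percentile 99.95), with OsGSTU12 (AK063773) at 2.64 and 2.51. The wild-type call ended with an offset of 10 (percentile 97.2) and without either array (94.1 each). Of 67 cytochrome P450 features 6 were higher and 0 lower in the wild type (median 0.07, percentile 88.3), among them cinnamate 4-hydroxylase again, and 4 higher and 1 lower in the knock-down (percentile 89.0). Of 41 UDP-glycosyltransferases 5 were higher and 2 lower in the wild type (median -0.04, percentile 18.1) and 5 higher and 0 lower in the knock-down (percentile 93.9). A salicylic acid glucosyltransferase (AK106302) had 3.48 and 1.99. Of 35 ABC transporters 2 were higher in the wild type (percentile 83.2) and 3 in the knock-down (percentile 56.1), and of 34 ubiquitin ligases 1, a RING finger protein (AK073728, 1.99 and 1.79), was higher in each (percentiles 77.6 and 81.7). Of 5 ethylene synthesis features 1, an aminocyclopropane carboxylate oxidase (AK058296), was higher in the wild type at 2.47 (list percentile 93.9) and had 0.72 in the knock-down (list percentile 6.5). AP2/ERF factors had 1 higher and 1 lower of 20 in the wild type (percentile 88.3) and 0 higher and 1 lower in the knock-down (percentile 93.7). The lower one was an AP2 domain protein (AK106517), at -1.95 in the wild type and -1.72 in the knock-down. The search missed a feature described as an AP2-related transcription factor (AK073812), called higher in both genotypes at 3.51 and 3.27. Heat shock proteins had 3 higher and 1 lower of 53 in the wild type (percentile 56.0) and 2 and 2 in the knock-down (percentile 59.1).

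Cell wall growth enzymes had 2 higher and 2 lower of 77 in the wild type (median 0.12, percentile 99.3) and 0 and 2 in the knock-down (median -0.07, percentile 1.78). In the knock-down 3 had a smaller and 0 a larger ratio (median difference -0.16, percentile 0.02, and 5.26 with only the orientation with treated RNA in Cy3). The 3 include alpha-expansin OsEXP5 (AK073572), which fell further in the knock-down, at -0.475 in the wild type and -2.219 in the knock-down. The calls in each genotype ended with the software's processed signals (percentiles 97.2 and 4.34) and without an array (45.8 without the wild-type array with treated RNA in Cy3, 17.4 and 51.0 without either knock-down array). A xyloglucan endotransglycosylase (AK070734) had 1.49 in the wild type and -1.03 in the knock-down. The 8 diterpenoid phytoalexin and plastid isoprenoid features had 0 calls in either genotype (percentiles 49.9 and 39.2). Among lists for other tissues, root uptake proteins had 6 of 36 features higher in the wild type (percentile 35.6) and 3 in the knock-down (percentile 41.8), including phosphate transporter Pht1-2 (AK101170) at 2.33 and 1.67 and metallothionein OsMT-1 (AK103445), a metal-binding protein, at 1.82 and -1.31. Photosynthesis proteins had 1 of 32 higher in the wild type (percentile 15.4) and 0 in the knock-down (percentile 42.0). Seed storage proteins had 1 of 12 (percentile 5.98) and 0 (percentile 15.4). The 1 was a late embryogenesis-abundant protein (AK061818), by its description no storage protein. Pollen and anther proteins had 1 of 6 higher in the wild type (median -0.28, percentile 1.09) and 1 in the knock-down (percentile 4.73). In both it was a calmodulin-binding protein (AK069986) that the calcium list also holds. The wild-type percentile of the pollen list was 28.2 without the array with treated RNA in Cy3 and, with a median of 0.19, 83.5 without the other.

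The median over 114 ribosomal protein features was -0.67 in the treated wild type, where 8 were lower by the 2-fold rule, and -0.18 in the knock-down, where 0 were. Loess normalisation, which bends with brightness, is argued against as the source, since with median centring the medians on the wild-type arrays were -1.48 and -0.55. A shift of a few members alone was not settled by the limits set beforehand. On both arrays 78.9% of members (90 of 114, 95% Wilson interval 70.6 to 85.4) were below 0 and 4 above 0. That is above the 60% set as the most such a shift would give, but it missed the 80% set for excluding it. Most members thus lay below 0. With the median itself at -0.67, these values argue against a shift of a few members alone on these arrays. The interval treats members as independent, though several can stem from the same gene. What shifted the median stays open, as no condition had replicate cultures.

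The 2 dye orientations agreed poorly among dim features, with r = -0.251 in the wild type and -0.306 in the knock-down across the dimmest of 4 brightness classes, against 0.89 and 0.865 in the brightest. A wrong dye label on an array of either genotype is argued against by the lower of the latter values, 0.865. Dye bias of single probes that repeats on every array is consistent with a correlation of 0.738 between genotypes in the orientation contrast of dim features. It cancels in the mean of both orientations and does not in single arrays.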
